A study of Mus musculus with 11 samples.

How the data were processed

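The deposited matrices held counts of unique molecular identifiers (UMIs) per barcode and gene for 11 single-cell libraries, taken here as the authors' counts per the file headers. The libraries were 4 of spinal leptomeninges with metastasis (LPT_MET), 4 of cerebellar tumour (Primary) and 3 of control spinal leptomeninges (LPT_WT). Alignment used Cell Ranger 3.0.2 and the mm10 genome, per the submitters' processing notes. Per the file headers, 6 libraries were made with Cell Ranger 3.0.2 on a list of 28010 features that held 12 transgene features, and 5 libraries with version 3.1.0 on a list of 31053 features. Tissue was dissociated with Liberase and libraries were prepared with 10x 3' chemistry of version 2 or 3, per the labels' protocols, which do not say which library had which. The barcodes of LPT_MET 1 and Primary 1 came from another list than those of the other 9 libraries, so mouse 1 differs from the others in this as well.

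Genes were matched by Ensembl ID, and 27514 IDs were in both feature lists. These genes held 99.8% to 99.9% of the UMIs of each library. Gene locations came from GENCODE M21, which listed 27403 of them.

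Cells were kept with at least 500 UMIs, 300 genes and at most 10% mitochondrial UMIs, which left 181573 of 202785 barcodes. Kept cells ranged from 4816 (LPT_WT 3) to 31331 (LPT_MET 4), with a median of 2197 UMIs (Primary 1) to 7923 (Primary 3). Doublets were scored per library with Scrublet, and the highest-scoring cells were removed at an expected rate of 0.8% per 1000 cells, at most 10%. This removed 186 (LPT_WT 3) to 3133 (LPT_MET 4) cells, or 3.85% to 10% of cells, while the automatic threshold of Scrublet would have removed 0.00927% (Primary 2) to 26.2% (LPT_MET 4).

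Counts were scaled to 10000 UMIs per cell and log-transformed. The steps after that were 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.5, over all libraries without batch correction. The 65 clusters were named from fixed marker sets, which needed at least 3 markers found in 10% of cells and a mean log2 level of the set at least 1.3 above the mean of the other clusters. Clusters with 25% or more called doublets, with haemoglobin beside markers of another class, or with few UMIs and no marker among their 10 leading genes stayed unnamed, bounds set after the data were seen. Names end in "-like" because they rest on transcripts alone.

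For gene tests the counts were summed per library and class over libraries with at least 20 cells of the class. The tests were edgeR quasi-likelihood F tests, which are two-sided, after filterByExpr and TMM normalization, with p adjusted by the Benjamini-Hochberg (BH) procedure and a threshold of 0.05. LPT_MET against LPT_WT carried the feature list as a covariate, and LPT_MET against Primary carried the mouse as a block. High against low burden used no covariate in tumour-like cells and kept the control libraries in the fit in fibroblast-like cells. Each log2 change is given with its standard error in brackets, and group levels are mean ± SD of CPM, the counts scaled to the library size with TMM factors. DESeq2 was run beside edgeR on the same models. The 27 fixed gene lists were tested with limma camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted by BH over the lists of a comparison. Results of fry are given below for only some lists. Single members of a list were adjusted by BH over that list alone, and this is stated where it is used.

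Shares were compared as logits with 0.5 added to each count, by two-sided exact permutation over all 35 splits for LPT_MET against LPT_WT and by two-sided exact sign flips over 16 signs for LPT_MET against Primary. Microglia-like cells were counted but not compared, because the leading genes of their cluster held 4 markers of macrophages beside 2 of microglia.

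Genes were named by a fixed rule. The rule took genes with adjusted p under 0.05, a mean of at least 20 CPM in the higher group, the same direction in every library or mouse, and a level no lower than the highest mean in any other class of that group divided by 3. Of these it named the 12 with the largest change in each direction, leaving out Xist, Y-linked, immunoglobulin, T-cell receptor, haemoglobin and unnamed predicted genes. It added up to 4 members per list with p under 0.05 over the list alone, and in every comparison Pdgfa to Pdgfd, Pdgfra, Pdgfrb, Bmp4, Bmp7, Gli1, Ptch1, Atoh1 and Mki67. The part of the rule on other classes is called the background criterion below, because RNA released by another class can account for genes that fail it. Some genes that the rule selects are not reported here. The comparisons, models, gene lists, marker sets, naming rule and 79 of the alternatives were chosen before the data were examined.

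The series text states that LPT_MET and Primary libraries of one number came from the same mouse. In tumour-like cells each LPT_MET library correlated best with its own Primary library (0.737, 0.506, 0.712 and 0.692 for mice 1 to 4, against at most 0.174 with another), so the mouse block was kept. In macrophage-like cells this held for mice 1 to 3 (0.678, 0.388 and 0.350), while LPT_MET 4 correlated at 0.163 with its own and 0.423 with Primary 3. The numbers of the control libraries named no shared mouse. Of 11 libraries, 2 control libraries, LPT_WT 1 and LPT_WT 3, carried sex-linked transcripts of the other sex than their labels. LPT_WT 1 had Xist at 623 CPM and no Y-linked transcripts. LPT_WT 3 had Xist at 0.0765 CPM and Y-linked transcripts at 184 CPM, against at most 0.0941 CPM in any other library.

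A self-test simulated counts with the means, library sizes and trended dispersions of each comparison and changed 200 genes by known folds, 50 genes per fold. It gave genes no dispersion of their own and no differences between libraries that many genes share. Recovery in the real data can therefore be lower. In fibroblast-like cells Eln, at a log2 change of 3.17, did not pass (edgeR BH adjusted p = 0.184). At folds of 2, 4, 8 and 16, edgeR recovered 24%, 86%, 100% and 98% in fibroblast-like cells, 22%, 90%, 98% and 100% in macrophage-like cells and 34%, 88%, 98% and 100% in endothelial-like cells for LPT_MET against LPT_WT. For LPT_MET against Primary it recovered 52%, 90%, 100% and 98% in tumour-like cells and 38%, 98%, 96% and 98% in macrophage-like cells. For high against low burden it recovered 6%, 54%, 80% and 92% in fibroblast-like cells and 0%, 38%, 66% and 94% in tumour-like cells. Unchanged genes called in error numbered 5, 6, 8, 4, 5, 8 and 1 in the same order.

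The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with random seed 1.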

Results

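The data were 11 single-cell RNA libraries of mice with medulloblastoma and of control mice. They held 4 libraries of spinal leptomeninges with metastasis (LPT_MET), 4 of the cerebellar tumours of the same mice (Primary) and 3 of control spinal leptomeninges (LPT_WT). Per the labels the tumour mice were Ptch1 heterozygous mutants and the controls Ptch1 wild type. On the labels tumour mice 1 to 4 were 20.0, 15.3, 27.3 and 20.9 weeks old, and controls LPT_WT 1 to 3 were 12.1, 23.0 and 20.9 weeks old. LPT_WT 1 and LPT_WT 3 carried sex-linked transcripts of the other sex than their labels, so their ages may be exchanged as well. By these transcripts LPT_WT 3 alone looked male, and no model held sex. In every comparison of LPT_MET with LPT_WT genotype goes with metastasis, so an effect of the genotype cannot be told apart from one of metastasis there. The libraries held 1420718280 UMIs in all. Per library this ranged from 24255958 (LPT_MET 2) to 311080022 (LPT_MET 3) in metastatic leptomeninges, from 81673382 (Primary 2) to 207815755 (Primary 3) in primary tumours and from 33167116 (LPT_WT 3) to 211781965 (LPT_WT 2) in controls.

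The first question was how much of each tissue was tumour. Metastatic leptomeninges held large and very unequal numbers of cells that carried transcripts of the granule neuron lineage, from which this tumour arises, while control leptomeninges held almost none. The tumour-like share was 42.4 ± 35.2% of cells in LPT_MET (5.41% to 86.5%) against 0.0271 ± 0.0470% in LPT_WT, where all 9 such cells lay in 1 library. The logit difference was 8.46 (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow). In the primary tumours the share was 82.2 ± 11.1%, from 66.9% in Primary 2 to 92.5%. Cells of unnamed clusters count as not tumour-like and made up 30.8% of Primary 2, most of them in clusters led by haemoglobin transcripts, 12.5% of Primary 1 and 2.94% to 13.7% of the other libraries. At resolution 0.8 such a cluster held 2683 cells of Primary 2, with haemoglobin at only 1.52% of its UMIs and the tumour markers as second-best set. Many of these cells may be tumour cells of low depth, so the share of Primary 2 may be too low. The logit difference of LPT_MET to Primary was -2.16 (two-sided exact sign-flip p = 0.125, the smallest that 16 sign flips allow).

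The next question was whether the other cells of the leptomeninges changed in number. Among cells that were not tumour-like, Schwann-like, mural-like and endothelial-like cells had lower mean shares with metastasis, and fibroblast-like, macrophage-like, T and NK-like and dendritic-like cells had higher ones. As shares of all cells, tumour-like cells included, the latter 4 turned, with logit differences of -0.0355, -0.0223, -0.21 and -0.0209. None of the 11 classes passed the adjusted threshold, which a class that changed alone could not reach with 35 splits, and 1 passed an unadjusted p of 0.05. Schwann-like cells made up 16.9 ± 8.29% in LPT_MET against 30.1 ± 5.88% in LPT_WT. Mural-like cells made up 21.8 ± 9.46% against 34.8 ± 9.01%, and endothelial-like cells 6.04 ± 2.51% against 10.1 ± 5.22%. Fibroblast-like cells made up 10.4 ± 6.99% against 4.73 ± 2.28%, and macrophage-like cells 15.9 ± 2.86% against 9.29 ± 7.84%. T and NK-like cells made up 3.56 ± 2.18% against 2.002 ± 1.25%, and dendritic-like cells 1.81 ± 0.945% against 0.935 ± 0.743%. Astrocyte-like cells, at 5.26 ± 9.11% (0.228%, 1.64%, 0.291% and 18.9% in LPT_MET 1 to 4) against 0.00309 ± 0.00535%, gave the unadjusted result (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow, BH adjusted p = 0.314). The edgeR test on cell counts, adjusted by BH, put the same class past the threshold (log2 change 9.85, adjusted p = 0.0232).

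**Figure D1:**
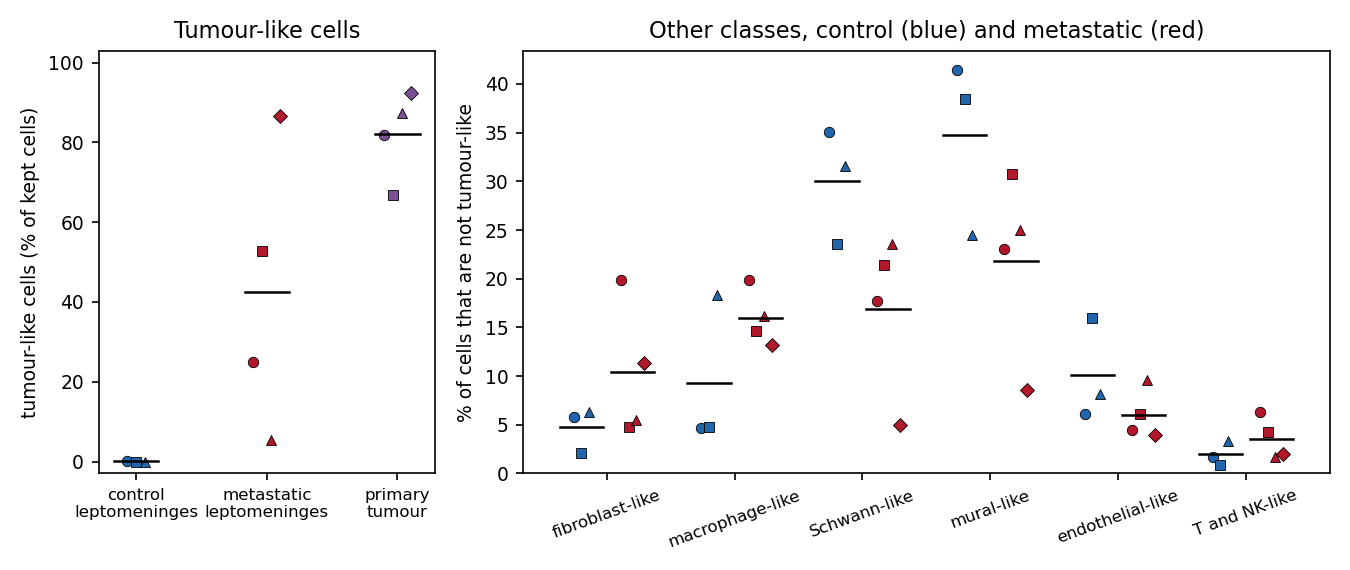
Shares of cell classes per library, tumour-like cells as a percentage of all cells and the other classes as a percentage of cells that were not tumour-like. Bars are group means, and circles, squares, triangles and diamonds mark replicates 1 to 4.

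The question in fibroblast-like cells was whether metastasis changes the matrix and the signals they express. With metastasis these cells carried more transcripts of basement membrane (collagen IV and XVIII, nidogen, agrin), of elastin and its crosslinking enzyme, of Timp1, of Aldh1a1 and Aldh1a2, and of the adhesion molecule Vcam1. Fibrillar matrix genes had a lower median change. Bmp4, Bmp7 and Pdgfrb had higher mean levels. None of these passed over all genes tested, because 0 of 10874 genes did in edgeR after BH adjustment. At an unadjusted p under 0.05 there were 1097 genes, and DESeq2 called 260.

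The basement membrane list held the largest set of changed members. Of 16 measured, 10 rose and 0 fell, adjusted over the list alone, and 6 did not pass (median log2 change 1.34, camera adjusted p = 1.9e-11, adjusted p = 0.42 with an estimated correlation). Col4a1 (mm10 chromosome 8: 11198423-11312826) had a log2 change of 2.08 (0.55), with 983 ± 883 against 191 ± 77.6 CPM, and its neighbour Col4a2 (chromosome 8: 11312805-11449287) 2.15 (0.49), with 519 ± 382 against 105 ± 39.0. Col18a1 (chromosome 10: 77052178-77166548) rose by 1.91 (0.47), Agrn by 1.89 (0.36) and Nid2 by 1.18 (0.30), each adjusted over the list alone. In the fibrillar matrix and crosslinking list 7 of 27 members rose and 1 fell over the list alone (median 0.59, camera adjusted p = 7.1e-07, adjusted p = 0.42 with an estimated correlation). The risen members included Eln (chromosome 5: 134702593-134747323) at 3.17 (0.49), with 387 ± 153 against 43.1 ± 23.1 CPM. They also included Timp1, an inhibitor of matrix proteases (chromosome X: 20870166-20874735), at 2.86 (0.48), with 328 ± 158 against 45.9 ± 6.73, and Lox (1.98 (0.40), 172 ± 68.8 against 46.1 ± 13.02). Tnc, at 3.76 (0.75) and 18.1 ± 12.3 CPM, failed the background criterion beside 187 CPM in astrocyte-like cells. Among matrix proteases 5 of 14 rose over the list alone (median 0.81, camera adjusted p = 0.016, adjusted p = 0.56 with an estimated correlation), with Adam12 at 2.04 (0.53). That median was 0.26 without LPT_MET 4 (camera adjusted p = 0.086) and -0.0948 without LPT_WT 2 (camera adjusted p = 0.31), and the fibrillar median was 0.24 without LPT_WT 2.

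In the endothelial activation and angiogenesis list 6 of 13 measured members rose over the list alone (median 1.34, 0.80 without LPT_WT 1, camera adjusted p = 0.00013, adjusted p = 0.42 with an estimated correlation). They included Vcam1 (1.90 (0.39), 191 ± 49.2 against 51.1 ± 22.7 CPM), Nrp1 (1.66 (0.31), 351 ± 112 against 115 ± 23.0) and Esm1 (2.28 (0.45), 178 ± 108 against 37.5 ± 27.3). The leptomeningeal transport and identity list did not move as a whole (median 0.07, -0.28 without LPT_MET 3 and -0.0601 without LPT_WT 3, camera adjusted p = 0.64), but 3 of 20 members rose over the list alone. They included the enzymes of retinoic acid synthesis Aldh1a2 (chromosome 9: 71215789-71296243), at 3.15 (0.57) and 310.4 ± 154 against 34.5 ± 13.4 CPM, and Aldh1a1 (1.47 (0.34), 136 ± 39.0 against 48.9 ± 15.9). Cdh11 (1.79 (0.43), 238 ± 51.9 against 68.7 ± 38.7 CPM) and Hgf (2.25 (0.57), 5.61 ± 1.06 against 1.24 ± 0.580) rose over their lists. Ccl2 (2.12 (0.40), 403 ± 174 against 93.1 ± 24.8 CPM) did so as well but failed the background criterion beside 1763 CPM in macrophage-like cells.

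Of 12 BMP and TGF-beta ligands 2 rose and 2 fell over the list alone (median 0.24, -0.11 without LPT_MET 3 and -0.21 without LPT_WT 2, camera adjusted p = 0.75). The risen members were Bmp4 (chromosome 14: 46383520-46390669; 1.23 (0.36), 151 ± 63.1 against 65.3 ± 17.6 CPM, edgeR BH adjusted p = 0.299 over all genes) and Tgfb1 (1.29 (0.29), 59.7 ± 17.2 against 26.0 ± 5.80), which failed the background criterion. Bmp5 fell by 1.01 (0.22) and Gdf11 by 1.21 (0.32). Bmp7 did not pass, at 0.80 (0.29) and 113 ± 31.1 against 64.9 ± 16.4. Fstl3, which binds activins, rose over the list of BMP antagonists (1.40 (0.30), 29.99 ± 7.08 against 11.5 ± 1.43). Pdgfrb (chromosome 18: 61045150-61085061) rose over the PDGF list alone, at 1.39 (0.36) and 233 ± 108 against 85.0 ± 23.8 CPM (camera adjusted p of the list = 0.11, 0.036 without LPT_MET 4). Pdgfra stayed at 361 ± 106 against 302 ± 54.6 CPM (0.18 (0.26)) and Pdgfa at 29.0 ± 15.01 against 21.5 ± 7.97 (0.24 (0.30)). Ptch1 did not pass at -2.14 (0.70), with 46.6 ± 57.7 against 135 ± 57.6 CPM, where the mutant Ptch1 allele of the LPT_MET mice is confounded with metastasis, nor did Gli1 at -0.78 (0.51), with 12.6 ± 11.0 against 18.7 ± 10.2.

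Of 10 mural markers measured in the same cells, Kcnj8 had a log2 change of 3.81, Abcc9 of 3.59, Ndufa4l2 of 2.95 and Vtn of 2.03. The others were at 0.94 (Higd1b), 0.55 (Notch3), 0.40 (Rgs5), 0.34 (Tagln), -0.50 (Acta2) and -2.04 (Myh11). Tumour-cell transcripts were present too, with Elavl3 at 8.62 ± 5.85 against 0 CPM (list median 1.58, 2.60 without LPT_WT 1 and 4.45 without LPT_WT 3, camera adjusted p = 1.9e-05, adjusted p = 0.42 with an estimated correlation). Proliferation transcripts such as Top2a (8.50 ± 6.74 against 0.330 ± 0.314 CPM) failed the background criterion. The fibroblast-like cells fell into 2 clusters, called the Pi16 cluster (led by Dcn, Pi16 and Mgp) and the Tgfbi cluster (led by Dcn, Apod and Lum, with Tgfbi next). Their cell numbers in the Pi16 and the Tgfbi cluster were 967 and 169, 131 and 39, 684 and 705, and 410 and 23 in LPT_MET 1 to 4, against 264 and 376, 105 and 353, and 151 and 140 in LPT_WT 1 to 3. In the Tgfbi cluster alone the median of the basement membrane list turned to -0.22 and Aldh1a2 to -0.33, and with LPT_MET 3 left out edgeR called 294 genes.

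**Figure D2:**
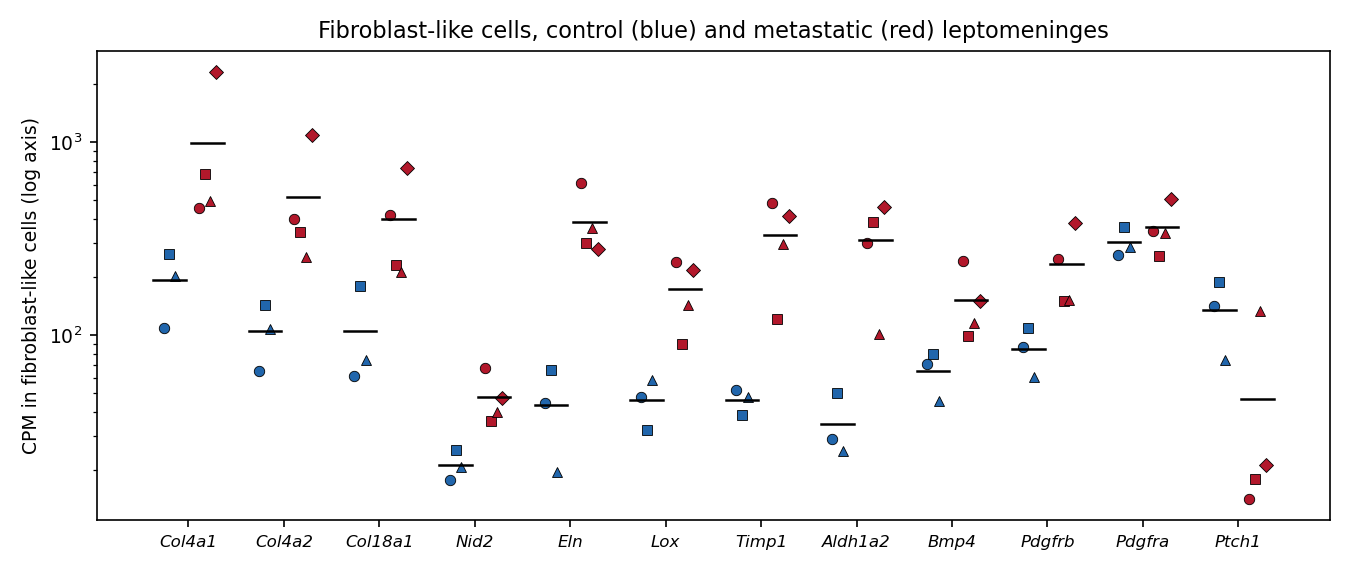
Levels of 12 genes in fibroblast-like cells per library, in CPM on a log axis. Control libraries are blue and metastatic libraries red.

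The question in macrophage-like cells of the leptomeninges was how metastasis changes their state. With metastasis these cells carried more of the B-cell attractant Cxcl13. Some members of the phagocyte lipid and lysosome list, such as Ctsd and Lgals3, were higher as well. Markers of resident border macrophages such as Pf4, Folr2 and Clec10a were lower. The inflammatory chemokine Ccl2, Tnf and immediate early transcripts were also lower than in controls. The log2 changes of 6 general macrophage markers were 0.11 for C1qa, 0.24 for C1qb, 0.19 for C1qc, 0.13 for Adgre1, -0.44 for Csf1r and 0.88 for Ms4a7. In edgeR 0 of 10875 genes passed after BH adjustment, 1326 had an unadjusted p under 0.05, and DESeq2 called 315.

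Cxcl13 (chromosome 5: 95956951-95961068) had the lowest edgeR BH adjusted p of the comparison, 0.0882, at 939.9 ± 283 against 66.4 ± 44.6 CPM (3.86 (0.46)). In the inflammatory cytokine and chemokine list it was 1 of 2 members that rose over the list alone, against 3 of 21 that fell (median -0.48, camera adjusted p = 0.068). That list passed with a median of -0.79 without LPT_MET 1 (camera adjusted p = 0.00047), -0.67 without LPT_MET 3 (camera adjusted p = 0.012) and -0.74 without LPT_WT 3 (camera adjusted p = 0.0011). The fallen members included Tnf (-1.26 (0.34), 819 ± 309 against 2099 ± 517 CPM) and Ccl2 (-1.32 (0.37), 1705 ± 797 against 4535 ± 1055). In the phagocyte lipid and lysosome list 4 of 19 rose and 0 fell over the list alone (median 0.70, camera adjusted p = 2.5e-09, adjusted p = 0.34 with an estimated correlation). Among them were Ctsd (2.23 (0.47), 2911 ± 1500.1 against 624 ± 105 CPM) and Lgals3 (1.33 (0.29), 320.3 ± 146 against 139 ± 58.8). The members Spp1 (2.01 (0.58), 230.4 ± 111 against 64.1 ± 41.6) and Cst7 (4.81 (1.04), 24.5 ± 19.0 against 0.671 ± 0.663) rose over the list and failed the background criterion. Of 14 tissue-resident macrophage genes 0 rose and 6 fell over the list alone (median -0.94, camera adjusted p = 2.1e-10, adjusted p = 0.37 with an estimated correlation). Pf4 (chromosome 5: 90772435-90773383) fell by 2.04 (0.33), from 2357 ± 450.2 to 545 ± 181 CPM, Folr2 by 0.99 (0.29), Cbr2 from 341 ± 227 to 111 ± 38.6 and Clec10a from 159.9 ± 54.4 to 66.8 ± 21.01.

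Of 19 hypoxia and glycolysis genes 3 rose over the list alone (median 0.41, camera adjusted p = 0.015, adjusted p = 0.34 with an estimated correlation). Without LPT_MET 3 the camera adjusted p was 0.095, and without LPT_WT 3 the median was 0.26. The risen members were Pkm (1.21 (0.27), 280.0 ± 106 against 129 ± 33.8 CPM), Pgam1 (1.18 (0.30), 148 ± 43.9 against 68.7 ± 21.6) and Aldoa (0.77 (0.23)). Gdf15 (1.35 (0.29), 182 ± 90.0 against 87.5 ± 44.8 CPM) rose over its list. Thbs1 (2.70) and Mmp14 (1.41) rose and failed the background criterion, and Mmp9 (-2.80) fell and failed it. Type I interferon genes had a median of -0.87 with 0 of 21 members past the list (camera adjusted p = 1.3e-07, adjusted p = 0.39 with an estimated correlation), and of -0.30 without LPT_WT 2 (camera adjusted p = 0.12). The immediate early transcripts Jun (-1.77 (0.36), 1643 ± 786 against 5305 ± 521 CPM), Atf3 (-1.94 (0.39), 1119 ± 476 against 4437 ± 767) and Egr1 (-1.57 (0.38), 1442 ± 868 against 3935 ± 864) were the 3 of 19 dissociation genes that fell over the list alone (median -0.97, camera adjusted p = 4.8e-12, adjusted p = 0.37 with an estimated correlation). PDGF ligands did not pass: Pdgfb was at -0.31 (0.28), Pdgfa at -0.35 (0.23) and Pdgfc at 1.90 (0.66).

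All 11 tumour-cell transcripts measured as background rose over their list alone (median 8.78, camera adjusted p = 2.5e-17, adjusted p = 0.34 with an estimated correlation). Examples were Sox11 at 98.9 ± 109 against 0.0764 CPM, beside 1176 CPM in tumour-like cells, and Neurod1 at 32.2 ± 43.4 against 0.0382. Blood transcripts moved the other way, with 3 of 5 fallen and 1 risen over the list alone (median -2.04, camera adjusted p = 0.0014, adjusted p = 0.37 with an estimated correlation) and the haemoglobin Hba-a1 at 0.826 ± 1.01 against 93.3 ± 80.6 CPM (-6.57 (1.18)). The blood median was -4.77, -4.17, -4.40 and -3.94 without LPT_MET 1 to 4, -4.70 without LPT_WT 1 and -3.85 without LPT_WT 3. A cluster led by Cxcl2, Cd74 and Il1b held 757, 313, 2931 and 160 cells of LPT_MET 1 to 4 and 399, 620 and 539 of LPT_WT 1 to 3. A cluster led by Lyz2, C1qb and C1qa held 269, 114, 92 and 296 against 1, 1 and 0, and a cluster led by C1qa, C1qb and Tyrobp 30, 29, 635 and 13 against 72, 284 and 182. The summed counts of the class cannot tell a change within cells from a change in this mix of clusters. In the Cxcl2 cluster alone edgeR called 38 genes, and with LPT_MET 3 left out it called 315.

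The question in endothelial-like cells was whether vessels of the leptomeninges take on an angiogenic state. No gene passed over all genes tested (0 of 10791 in edgeR, 608 at an unadjusted p under 0.05, 93 in DESeq2). In the endothelial activation and angiogenesis list 2 of 20 members rose over the list alone (median 0.61, camera adjusted p = 0.013, adjusted p = 0.53 with an estimated correlation). They were Dll4, a Notch ligand of tip cells (chromosome 2: 119325784-119335962), at 1.34 (0.34) and 43.0 ± 16.5 against 16.9 ± 6.33 CPM, and Mcam (1.68 (0.44), 30.6 ± 16.4 against 9.04 ± 1.41; it failed the background criterion). The median of that list was 0.0552 without LPT_MET 2, 0.39 without LPT_MET 4, 0.65 without LPT_WT 1 and 0.40 without LPT_WT 2 (camera adjusted p = 0.68, 0.13, 0.055 and 0.070), and 1.06 without LPT_WT 3. The basement membrane list had a median of 1.31 with 0 of 13 members past the list (camera adjusted p = 0.00073, adjusted p = 0.46 with an estimated correlation). It was 0.50 without LPT_MET 2 (camera adjusted p = 0.24) and 0.71 without LPT_MET 4. The hypoxia gene Adm rose over its list at 1.85 (0.39), 51.3 ± 46.7 against 15.5 ± 7.69 CPM (1 of 16, median 0.45, camera adjusted p = 0.00038, adjusted p = 0.32 with an estimated correlation).

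In the phagocyte lipid and lysosome list Lgals1 (1.47, 59.9 ± 18.2 against 20.9 ± 8.68 CPM) and Cd63 (1.40, 86.9 ± 32.2 against 31.6 ± 3.51) rose, 2 of 14, and failed the background criterion beside fibroblast-like cells. The list had a median of 0.67 (camera adjusted p = 0.00029, adjusted p = 0.15 with an estimated correlation, fry adjusted p = 0.025). Of 7 BMP and TGF-beta ligands Inhbb rose (2.90 (0.87), 7.76 ± 6.80 against 1.13 ± 0.479 CPM) and Bmp2 fell by 1.29 (0.27), the latter failing the background criterion. Bmp4 (0.50 (0.21)), Pdgfb (-0.19 (0.21), 149.7 ± 26.5 against 166 ± 27.1 CPM), Pdgfa (-0.73) and Pdgfd (0.15) did not pass. Tumour-cell transcripts rose here as well, 7 of 9 over the list alone (median 7.90, camera adjusted p = 4.0e-26, adjusted p = 0.15 with an estimated correlation). Sox11 was at 69.3 ± 90.8 against 0.397 CPM and Barhl1 at a log2 change of 9.63. Sfrp1 (9.26), the astrocyte transcript Slc1a2 (6.28), Mmp14 (3.42) and Pcna (1.01) rose over their lists and failed the background criterion.

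The question in tumour-like cells was what differs between metastasis and the primary tumour of the same mouse. Metastatic tumour-like cells carried more of the BMP targets Id1 and Id3, more Srebf2, a regulator of sterol synthesis, and less Txnip, an inhibitor of thioredoxin that responds to glucose. In edgeR 4 of 14635 genes passed after BH adjustment, 3 higher and 1 lower, while 2441 had an unadjusted p under 0.05 and DESeq2 called 1106 (715 higher and 391 lower).

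Srebf2 (chromosome 15: 82147181-82205379) rose by 1.45 (0.11), from 25.4 ± 11.0 to 72.0 ± 39.2 CPM (edgeR BH adjusted p = 0.0316). Txnip (chromosome 3: 96557957-96561883) fell by 1.68 (0.12), from 49.9 ± 17.8 to 15.8 ± 6.74 CPM (edgeR BH adjusted p = 0.0270). Id3 (chromosome 4: 136143497-136145755) rose by 4.39 (0.32), from 6.47 ± 3.99 to 130.0 ± 73.1 CPM, and Cxcl1 by 3.73 (0.27), from 0.538 ± 0.283 to 7.75 ± 5.10. Both failed the background criterion, beside 3917 CPM of Id3 and 2519 CPM of Cxcl1 in mural-like cells of the same libraries. Without the mouse block edgeR called 1 gene, which was not among the 4, and with mouse 3 left out it called 0.

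Of 10 BMP response genes 7 rose and 1, Hey1, fell over the list alone, while 1 rose and 0 fell over all genes tested (median 0.92, 0.56 without mouse 3, camera adjusted p = 1.2e-11, adjusted p = 0.35 with an estimated correlation). Id1 (chromosome 2: 152736251-152737410) rose over the list at 3.06 (0.31), 375 ± 140.3 against 44.0 ± 11.4 CPM (edgeR BH adjusted p = 0.0573 over all genes), and Atoh8 (3.88 (0.91)) and Smad9 (1.68 (0.36)) did so at under 5 CPM and failed the background criterion. Inflammatory cytokines and chemokines rose in 11 of 19 members over the list alone (median 2.20, camera adjusted p = 5.4e-16, adjusted p = 0.49 with an estimated correlation). Cxcl2 was at 16.04 ± 14.3 against 1.503 ± 2.03 CPM and Ptgs2 at 2.05 against 0.0401. Both failed the background criterion, beside 14798 CPM of Cxcl2 in macrophage-like and 605 CPM of Ptgs2 in mural-like cells. The dissociation and immediate early list rose in 6 of 19 members over the list alone (median 1.46, 2.20 without mouse 2 and 0.76 without mouse 3, camera adjusted p = 5.8e-09, adjusted p = 0.49 with an estimated correlation). Egr1 was at 1361 ± 1051 against 236 ± 192 CPM (2.75 (0.77)). Nr4a1 was at 3.81, Zfp36 at 2.58 and Ier3 at 1.66, and all of these but Egr1 failed the background criterion. Transcripts of other cell types moved with these, namely Bgn (3.09) and Cd74 (1.27). In the fibrillar list 7 of 24 members rose and 1 fell over the list alone (median 0.67, camera adjusted p = 1.5e-06, adjusted p = 0.49 with an estimated correlation).

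Of 18 type I interferon genes 2 fell over the list alone, Usp18 (-2.77 (0.39), 0.217 against 2.06 CPM) and Ifi44 (-2.54 (0.45)), which both failed the background criterion (median -1.40, -0.74 without mouse 1, camera adjusted p = 3.4e-05, adjusted p = 0.49 with an estimated correlation). Atoh1 (chromosome 6: 64729125-64731245) fell over the hedgehog response list alone, by 1.03 (0.23), from 145 ± 25.05 to 73.8 ± 29.3 CPM (edgeR BH adjusted p = 0.156 over all genes). It was the only one of 13 members to do so (median 0.0559, camera adjusted p = 0.58; -0.0878, -0.0770 and -0.0565 without mice 1, 3 and 4). Gli1 (0.29 (0.23), 46.1 against 34.4 CPM), Ptch1 (-0.09 (0.15), 56.1 against 56.5) and Mki67 (0.01 (0.16), 413 ± 179 against 394 ± 156) did not pass, nor did any of 25 proliferation genes (median 0.00323, camera adjusted p = 0.94; -0.0384, -0.0634 and -0.0818 without mice 2 to 4). Pdgfra was at 0.09 (0.59) and Pdgfa at -0.02 (0.18).

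The tumour-like cells of mouse 2 differed in 1 whole chromosome: the median log2 ratio of LPT_MET to Primary over chromosome 8 was -0.52, and the largest of any other autosome was 0.0580 in size. Chromosome 8 made up a median of 6.44% of UMIs in Primary 2 cells with Xist, 4.63% in LPT_MET 2 and 4.18% to 4.54% in tumour-like cells of the other mice. The largest in mouse 1 was -0.23 (chromosome 13) and in mouse 3 -0.26 (chromosome 6). Xist stood at 2.69 CPM in tumour-like cells of LPT_MET 2 against 1191 in those of Primary 2, while the other cells of LPT_MET 2 had 516. In mouse 4 it was low in tumour-like cells of both tissues (0.817 and 0.321 CPM) and 389 and 344 in their other cells. Xist was singled out after its values were seen.

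**Figure D3:**
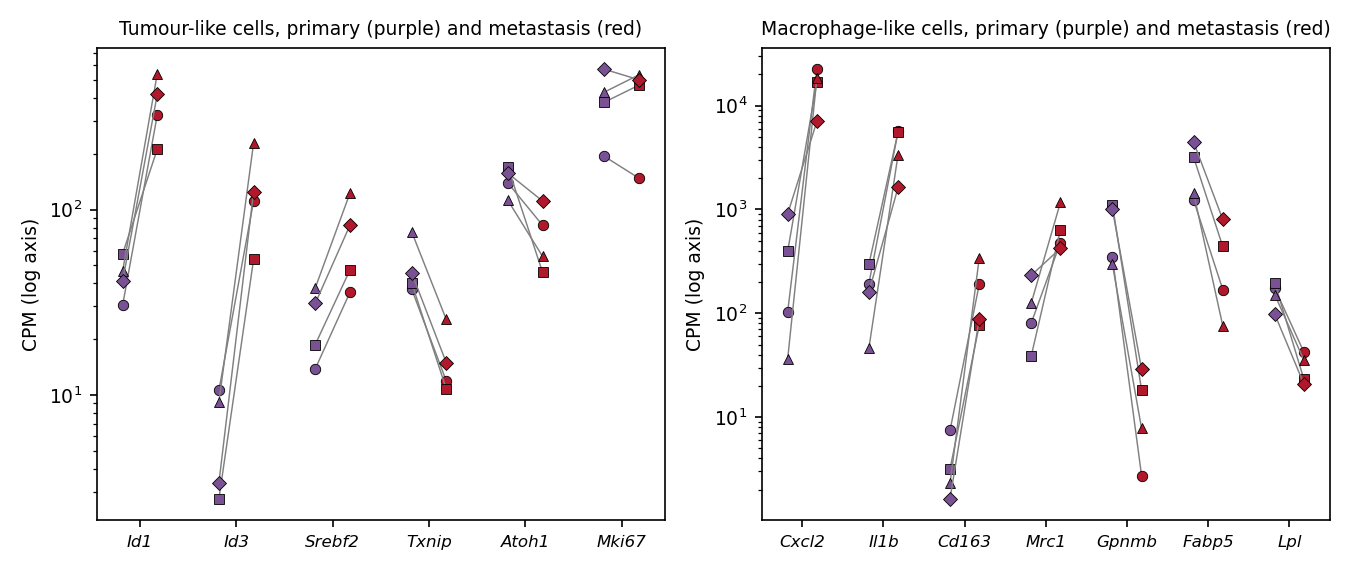
Levels in tumour-like and macrophage-like cells of primary tumour and metastasis in CPM on a log axis. Lines join the tissues of the same mouse.

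**Figure D4:**
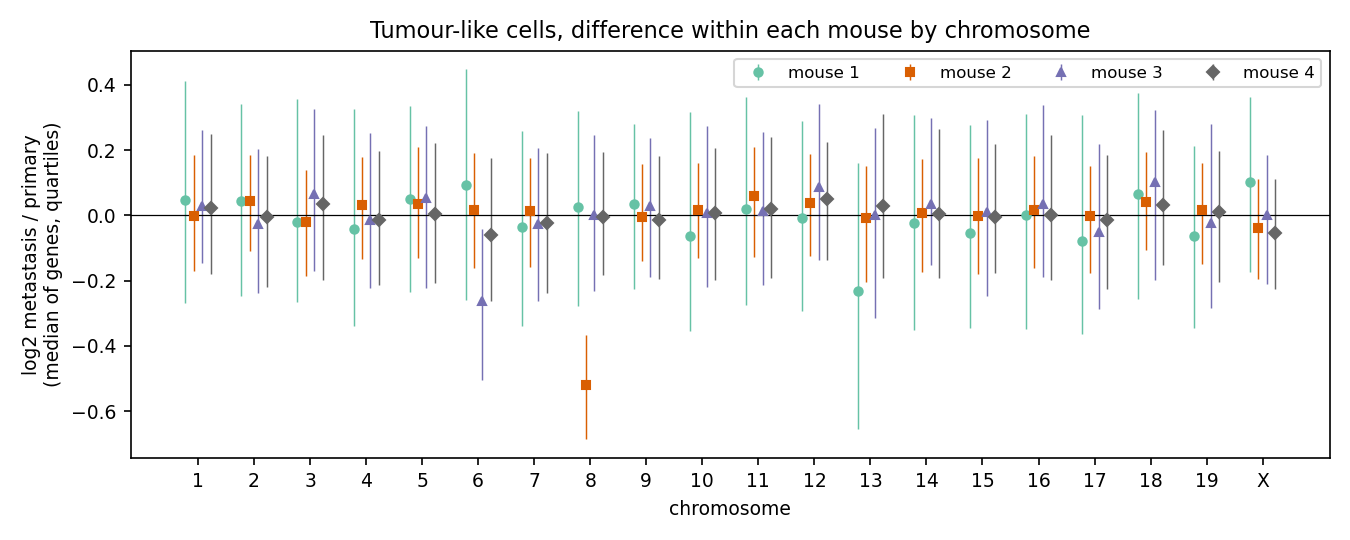
Median and quartiles of the log2 ratio of metastasis to primary tumour over the genes of each chromosome in tumour-like cells of mice 1 to 4.

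The question in macrophage-like cells of matched tissues was how those beside the metastasis differ from those in the primary tumour. This was the comparison with the most changed genes. Macrophage-like cells of metastatic leptomeninges carried the markers of resident border macrophages (Cd163, Mrc1, Clec10a, Cbr2, Vsig4) and high levels of neutrophil and monocyte attractants and Il1b. Immediate early genes were higher there as well. A response to dissociation was not tested in this comparison and stays open for the attractants and Il1b. Those of primary tumours carried a lipid-handling phagocyte programme (Gpnmb, Fabp5, Lpl, Itgax), Igf1 and Atp6v0d2. The comparison sets leptomeninges against cerebellar tumour, so a difference between the tissues cannot be told apart from an effect of metastasis. Against control leptomeninges, macrophage-like cells of LPT_MET had lower Cd163 (log2 change -0.80), Mrc1 (-0.87), Clec10a (-1.20) and Cbr2 (-1.50). In edgeR 843 of 10308 genes passed after BH adjustment, 553 higher and 290 lower, and DESeq2 called 1422. The macrophage-like cells of Primary 1 to 4 numbered 179, 94, 636 and 46. At resolution 0.8 a macrophage-like cluster led by Lyz2, C1qb and C1qa held 2467, 152, 1322 and 45, called doublets included. Most such cells of Primary 1 were thus left out here, so the counts do not cover all macrophage-like cells of the primary tumours. Of the 843 genes 610 met the background criterion.

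The 12 named higher genes were Areg (chromosome 5: 91139599-91148432; 8.84 (0.44), 215 ± 184 against 0.171 ± 0.342 CPM), Cxcl1 (7.61 (1.13), 2179 ± 864 against 15.9 ± 13.02), Saa3 (6.82 (1.23), 550.1 ± 429 against 15.4 ± 30.04), Vsig4 (6.59 (0.58), 32.1 ± 25.5 against 0.521 ± 0.783), Cxcl13 (6.44 (1.40), 1070.5 ± 333 against 63.7 ± 120.5) and Cxcl2 (6.38 (1.26), 16242 ± 6532 against 361 ± 397). The others were Cd163 (chromosome 6: 124304656-124330527; 5.92 (0.55), 174 ± 122 against 3.64 ± 2.62), Mir155hg (5.69 (1.07)), Bmp2 (4.99 (0.63), 69.6 ± 53.9 against 3.09 ± 2.70), Ccl7 (4.84 (0.93), 1781 ± 691 against 131 ± 176), Gpr132 (4.83 (0.44)) and Alox5 (4.76 (0.86)). The 12 named lower genes were Gpnmb (chromosome 6: 49036546-49070929; -5.75 (0.37), 14.4 ± 11.6 against 692 ± 429 CPM), Htr2b (-5.71 (0.60)), Adgrg3 (-5.70 (0.73)) and Atp6v0d2, a subunit of the lysosomal proton pump (-5.52 (0.30), 4.24 ± 2.21 against 209 ± 114). Further ones were Cdo1 (-4.90), Cd5l (-4.66 (0.96), 13.4 against 424 ± 609), Fabp5 (-3.11 (0.32), 372 ± 326 against 2592 ± 1538), Mmp2 (-2.92), Hpse (-2.70), Spint1 (-2.69), Fabp3 (-2.67) and Slc6a8 (-2.65).

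Of 21 inflammatory cytokines and chemokines 15 rose and 1, Cxcl9, fell over the list alone, and 11 rose and 0 fell over all genes tested (median 3.04, camera adjusted p = 7.6e-15, adjusted p = 0.42 with an estimated correlation). Il1b was at 4059.6 ± 1929.5 against 173 ± 102.9 CPM (4.67 (0.53)). Of 14 tissue-resident macrophage genes 11 rose over the list alone and 4 over all genes (median 2.39, camera adjusted p = 7.2e-10, adjusted p = 0.53 with an estimated correlation). Mrc1 was at 678 ± 341 against 119 ± 83.2 CPM (2.69 (0.55)), Clec10a at 2.96 and Cbr2 at 3.56. Of 19 phagocyte lipid and lysosome genes 0 rose and 16 fell over the list alone, 13 over all genes (median -1.31, camera adjusted p = 6.5e-19, adjusted p = 0.42 with an estimated correlation, fry adjusted p = 0.025). Beside Gpnmb and Fabp5 these included Itgax at -2.54 (0.29), and Lpl at -2.34, which failed the background criterion. Dissociation and immediate early genes rose in 16 of 19 members over the list alone and in 3 over all genes (median 3.29, camera adjusted p = 2.7e-11, adjusted p = 0.53 with an estimated correlation). Egr1 was at 1643 ± 1001 against 90.9 ± 70.1 CPM. Interferon genes were mixed (3 rose and 5 fell of 21 over the list alone, median -0.26, camera adjusted p = 0.33), with a median of -0.55 without mouse 2 (camera adjusted p = 8.9e-05) and 0.0449 without mouse 4. So were hypoxia and glycolysis genes (5 and 5 of 18, median 0.00649, camera adjusted p = 0.98, -0.0610 without mouse 1 and -0.26 without mouse 3, with Pkm at -0.79 (0.15) and Pgam1 at -0.74). C4b rose (3.46, 367 ± 235 against 33.7 ± 19.5 CPM), and Igf1 (-1.57 (0.22), 98.1 ± 28.0 against 291 ± 63.2), Mmp14 (-1.58) and Pdgfc (-1.21 (0.29)) fell.

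The cluster led by Cxcl2, Cd74 and Il1b held 9, 9, 1 and 4 cells of Primary 1 to 4, and the cluster led by Lyz2, C1qb and C1qa 140, 66, 568 and 30. The count of 843 fell to 504 without the mouse block and to 89 where clusters with more called doublets were named too. With 1 mouse left out it ranged from 10 (without mouse 1) to 2014 (without mouse 4, whose primary tumour gave 46 macrophage-like cells).

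The last question was whether the metastatic burden on the labels, high in mice 2 and 4 and low in mice 1 and 3, goes with expression in the leptomeninges. Mice of high burden were 15.3 and 20.9 weeks old and those of low burden 20.0 and 27.3. An effect of age was not tested apart from that of burden. With high burden fibroblast-like cells had lower mean levels of Cyr61 and Ctgf, which are known as YAP targets. Neither YAP activity nor a response to dissociation was tested as the source. Tumour-like cells had less of antigen presentation and cytokine transcripts, which other cells express. In fibroblast-like cells 0 of 11376 genes passed in edgeR after BH adjustment, 678 had an unadjusted p under 0.05 and DESeq2 called 24. The count was 69 without LPT_MET 1, whose barcodes came from another list than those of LPT_MET 2 to 4, 15 without LPT_MET 3 and 2 without LPT_MET 2. Of 25 growth factors and guidance ligands 0 rose and 4 fell over the list alone (median -0.62, camera adjusted p = 0.00013, 0.12 without LPT_MET 4, adjusted p = 0.23 with an estimated correlation). Among them Cyr61 (chromosome 3: 145646976-145649981) was at 76.3 ± 40.9 against 359 ± 229.5 CPM (-2.20 (0.36), edgeR BH adjusted p = 0.302), Ctgf at 196 ± 27.3 against 845 ± 339 (-1.96 (0.55)) and Wnt6 at 24.3 ± 19.4 against 87.1 ± 15.1 (-2.13 (0.42)). The BMP pseudoreceptor Bambi fell over its list from 42.8 ± 1.48 to 15.8 ± 9.25 CPM (-1.64 (0.41)). Of 14 endothelial activation genes 1, Col4a1, rose and 7 fell over the list alone (median -1.55, camera adjusted p = 0.00035, adjusted p = 0.23 with an estimated correlation). This median was -0.81 without LPT_MET 3, -0.88 without LPT_MET 4 (camera adjusted p = 0.31) and -0.80 without LPT_WT 2. Of 13 antigen presentation genes 0 rose and 5 fell (median -0.59, -1.13 without LPT_MET 4, camera adjusted p = 1.5e-07, adjusted p = 0.23 with an estimated correlation), with Cd74 at -3.03. Cd74 failed the background criterion, as did the protease Plau, which rose over its list at 2.86. Pdgfrb (0.29), Pdgfra (0.10), Bmp4 (-0.50), Bmp7 (-0.33) and Ptch1 (-1.60 (0.83)) did not pass.

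In tumour-like cells 0 of 13304 genes passed in edgeR after BH adjustment, 566 had an unadjusted p under 0.05 and DESeq2 called 68. Antigen presentation genes fell in 7 of 12 members over the list alone (median -2.38, camera adjusted p = 1.3e-19, adjusted p = 0.28 with an estimated correlation). Inflammatory cytokines and chemokines fell in 11 of 19 over the list alone (median -2.13, camera adjusted p = 1.3e-19, adjusted p = 0.28 with an estimated correlation). Cd74 (-3.38, 2.77 against 28.4 CPM) and Dcn (-2.44) failed the background criterion, as did every other member of these lists that the naming rule took. RNA released by other classes was not tested as the source of these changes and stays open. Haemoglobin and other blood transcripts rose in 4 of 5 members and fell in 1 over the list alone (median 3.16, 2.34 without LPT_MET 3 with a camera adjusted p of 0.33, camera adjusted p = 3.7e-09, adjusted p = 0.28 with an estimated correlation). Hbb-bs was at 39.3 ± 4.82 against 3.42 ± 2.05 CPM. Ptch1 (1.04 (0.56), 76.0 ± 28.4 against 37.1 ± 22.4 CPM), Mki67 (0.52), Gli1 (0.22) and Atoh1 (0.20) did not pass. With 2 libraries on each side, the self-test recovered 0% of genes at a fold of 2 and 38% at a fold of 4.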

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

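The tests of the Id1 and Id3 result, the tests within the fibroblast-like clusters and of pericytes, the tests by relabelled libraries and the interaction test were chosen only after the results were seen, while the background tests of the fibroblast-like matrix lists were written before their values.

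Id1 and Id3 were higher in tumour-like cells of metastasis than in the primary tumour in all 4 mice, which is in line with a BMP response in the leptomeninges, where fibroblast-like cells had the highest Bmp4 levels. RNA released by local cells is a second explanation, because mural-like cells carried far more Id3, but the observed level was at least 8.28 times the level predicted from the marker transcripts of 5 local classes, which argues against it. A response to dissociation is a further explanation, and there the median of the immediate early genes was -0.39 in mouse 2, in which Id1 was at 1.86 and Id3 at 3.87, against 1.72 in mouse 1, 2.86 in mouse 3 and a value above 1 in mouse 4. A single mouse cannot decide, so this explanation stays open. A BMP assay of tumour cells sorted without warm digestion would tell the explanations apart.

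The basement membrane and the fibrillar matrix list were higher in fibroblast-like cells with metastasis, which may be a change within cells or a shift from the Tgfbi to the Pi16 cluster. Within the Pi16 cluster alone the basement membrane list had a median of 1.06 (camera adjusted p = 6.0e-10, adjusted p = 0.52 with an estimated correlation), and 7 of 16 members rose over the list alone. This argues against a shift as its sole source, although the median was -0.22 in the Tgfbi cluster. Within the Pi16 cluster the fibrillar list had a median of 0.24 (camera adjusted p = 0.071, adjusted p = 0.69 with an estimated correlation), down from 0.59, as a shift between clusters would give. Released RNA from other classes is a further explanation, but the median ratio of observed to predicted levels was at least 21.8 for the basement membrane list and 37.4 for the fibrillar list in every metastatic library, which argues against it. Pericytes sorted with these cells are another, because 4 of 10 mural markers had log2 changes above 2. The pericyte marker Rgs5 allowed a share of only 0.345% to 12.6% of them in the 4 metastatic libraries, and at that share the median ratio of observed to predicted levels was at least 20.1 and 37.3 for the same lists, which argues against pericytes as their source. An effect of the Ptch1 genotype was not tested and stays open.

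Relabelling the libraries asked whether chance alone gives as many genes, with the real split counted among 34 splits that could be fitted. In fibroblast-like, macrophage-like, endothelial-like and Schwann-like cells the real count past adjustment was 0, which all 34 splits reach by construction, so only the counts at an unadjusted p under 0.05 are informative there. In fibroblast-like cells 3 splits gave at least the real 1097 such genes, with up to 2024, and the highest count past adjustment was 396. In macrophage-like cells 5 gave at least 1326, with up to 2761, and the highest past adjustment was 576. The splits with 396, 2024, 576 and 2761 genes were the same one, which set LPT_MET 3 with the controls against LPT_MET 1, 2 and 4, and this points to a structure of the samples. Among the leptomeningeal libraries LPT_MET 3, LPT_MET 4 and LPT_WT 2 were made with Cell Ranger 3.1.0. The source of the structure was not tested. In endothelial-like cells 10 gave at least 608, with up to 1822, and the highest past adjustment was 3. In Schwann-like cells 10 gave at least 486, with up to 2981, and the highest past adjustment was 889. Both of these came from a split that set LPT_MET 1, 3 and 4 with LPT_WT 2 apart, which points to a structure of the samples as well. On the unadjusted counts chance can not be excluded in these 4 classes, nor in T and NK-like cells, where 2 splits reached the real 10 genes, with up to 18, or mural-like cells, where 5 reached the real 2, with up to 9. In dendritic-like cells only the real split reached its 207 genes, 1 of 34, and the highest other gave 131. That share is under 0.05 for the class taken alone, but it is the smallest that 34 splits allow, so chance cannot be excluded over the 7 classes tested. With 1 library left out the 207 genes became 18 to 389, and the class may mix B and dendritic cells. Relabelling cannot tell a change of that mix from a change of expression. The matched comparisons had 8 splits, too few for a share under 0.05: in tumour-like cells 1 split, the real one, gave 4 genes and the highest other 0, and in macrophage-like cells 1 split, the real one, gave 843 and the highest other 0.

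Single libraries stood apart from the others of their group in 30 of 209 tested groups, where chance alone flags about 1 in 20, or 10.45, of independent and normally distributed values. The values tested were CPM and percentages, which are skewed, most flags were of a highest library, and several genes can share a source. The excess therefore cannot show that libraries stood apart beyond chance. In fibroblast-like cells of LPT_MET the highest library stood apart for Col4a1 (2299 CPM), Fstl3 (40.5), Ptch1 (133), Gli1 (29.0) and Top2a (18.6). In macrophage-like cells of LPT_MET beside the controls it did so for Egr1 (2732) and Neurod1 (96.8). In endothelial-like cells of LPT_MET it did so for Cd63 (135), Pdgfb (189), Barhl1 (68.2), Sfrp1 (113) and Sox11 (205). In tumour-like cells the highest Primary library stood apart for Cxcl2 (4.52), Nr4a1 (5.30), Pdgfa (108) and Usp18 (6.53), the highest LPT_MET library for Usp18 (0.560) and the lowest LPT_MET library for Mki67 (148). In macrophage-like cells of the matched tissues the highest Primary library stood apart for Areg (0.683), Saa3 (60.5), Cxcl13 (244), Cd5l (1326) and Htr2b (97.0), and the lowest for Fabp3 (21.2). There the highest LPT_MET library stood apart for Egr1 (3129), Cdo1 (8.15) and Adgrg3 (1.297), and the lowest for Fabp3 (0.698). Among shares the highest LPT_MET library stood apart for astrocyte-like cells (18.9%) and neutrophil-like cells (2.01%).

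The difference between metastasis and primary tumour in macrophage-like cells depended on burden for 203 genes in edgeR after BH adjustment (88 higher and 115 lower with high burden, 1618 at an unadjusted p under 0.05), led by S100a8 (-7.20), Nr4a1 (-4.23), Klf2 (-3.40), Il1rn (-3.21), Osm (-3.18) and Ier3 (-3.15), on only 2 residual degrees of freedom. Of the 88 higher genes 87 failed the background criterion, 67 of them with their highest level in tumour-like cells. Of the 115 lower genes 31 failed it and 13 were among the 19 dissociation and immediate early genes (median -3.07, camera adjusted p = 3.9e-43, adjusted p = 0.37 with an estimated correlation, fry adjusted p = 0.078). S100a8 is a neutrophil transcript, at 92632 CPM in neutrophil-like cells, and 1 of 3 blood transcripts fell over all genes (median -7.20, camera adjusted p = 8.5e-05, adjusted p = 0.37 with an estimated correlation, fry adjusted p = 0.37). RNA released by tumour cells or neutrophils and a response to dissociation therefore stay open. Tumour-like cells had 0 such genes and 419 at an unadjusted p under 0.05.

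EGFP transcripts, which only 6 libraries could hold, were found in 4.94% of tumour-like cells of LPT_MET 1 (94 of 1901, exact 95% interval 4.01% to 6.02%, median 6898 UMIs) and in 7.15% of those of LPT_MET 2 (282 of 3946, exact 95% interval 6.36% to 7.995%, median 3062 UMIs). In LPT_MET 1 other classes with at least 100 cells ranged from 0.198% of Schwann-like cells (2 of 1012, median 1937.5 UMIs) to 1.74% of neutrophil-like cells (2 of 115, exact 95% interval 0.211% to 6.14%, median 9431 UMIs). Near the depth of the tumour-like cells, the share was 0.618% of macrophage-like cells (7 of 1133, exact 95% interval 0.249% to 1.27%, median 6427 UMIs) and 0.792% of fibroblast-like cells (9 of 1136, exact 95% interval 0.363% to 1.499%, median 5922 UMIs). In LPT_MET 2 it was 0 of 517 macrophage-like cells, where 3 counts would be 0.580% (median 2502 UMIs), 0.0918% of mural-like cells (1 of 1089, median 2184 UMIs) and 2.07% of unnamed cells (9 of 435, median 1108 UMIs). In Primary 1 the share of tumour-like cells, 4.82% (761 of 15781), lay within the 2.96% (neutrophil-like) to 6.58% (T and NK-like) of other named classes with at least 50 cells, so no signal above background is shown there. In Primary 2 it was 33.2% (2191 of 6596, exact 95% interval 32.1% to 34.4%, median 8753.5 UMIs), against 3.19% of macrophage-like cells (3 of 94, exact 95% interval 0.663% to 9.04%, median 9173.5 UMIs). Unnamed cells of Primary 2 had 8.99% (273 of 3036, median 1384.5 UMIs). Their EGFP level was 52.6 CPM, against 48.9 in tumour-like and 2.27 in macrophage-like cells. Many of them may thus be tumour cells, but this level cannot tell tumour cells from droplets that hold RNA released by tumour cells.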

How the results depend on the processing

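The tests with single clusters, with an uncapped doublet rate, with clusters of more called doublets named, with shares among named cells and of the further classes under other settings were chosen only after the results were seen, and every alternative that was fixed beforehand was run. The share of tumour-like cells kept its direction throughout. The counts of genes past edgeR BH adjustment moved with the tool, the low-count filter, the clusters named and the libraries used, and the cause was not tested for any count that changed. Of the values per gene 44 reversed, 2213 stayed, 251 became stronger and 143 weaker, and of those per list 5 reversed, 604 stayed, 10 became stronger and 30 weaker.

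With DESeq2 in place of edgeR the counts were 260 for fibroblast-like, 315 for macrophage-like and 93 for endothelial-like genes of LPT_MET against LPT_WT, 1106 for tumour-like and 1422 for macrophage-like genes of LPT_MET against Primary (839 shared with the 843), 24 and 68 for fibroblast-like and tumour-like genes of high against low burden, and 511 for the further classes in place of 219. Of the counts of single further classes under other settings 32 moved by over 1.5 times and 12 did not. Without the low-count filter they were 790, 885, 555, 74, 1229, 22 and 105 in the same order. With doublets kept they were 109 for macrophage-like and 34 for endothelial-like genes of LPT_MET against LPT_WT, 7 for tumour-like genes of LPT_MET against Primary, and 1 for tumour-like genes by burden, and with an uncapped doublet rate 5 for macrophage-like genes of LPT_MET against LPT_WT. RLE factors gave 2 and the stricter cell filter 1 for tumour-like genes by burden. Leaving out genes that failed the background criterion gave 2 in place of 4 for tumour-like genes of LPT_MET against Primary. At least 50 cells per library gave 2014 for macrophage-like genes of LPT_MET against Primary (831 shared), because it removed mouse 4, and naming clusters with more called doublets gave 89 (85 shared). The fit with LPT_MET libraries only gave 1 for fibroblast-like genes by burden. The edgeR test on cell counts gave 1 class in place of 0.

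The pairing of LPT_MET and Primary by mouse mattered: without the mouse block tumour-like genes fell to 1 (0 shared) and macrophage-like genes to 504 (408 shared), and in tumour-like cells Pdgfa turned to 0.000530 and Pdgfra to -0.0638. Taking the replicate numbers of LPT_MET and LPT_WT as a block, although no mouse was shared, gave 36 fibroblast-like, 114 macrophage-like and 34 endothelial-like genes. The numbers did not pair in the data, with own correlations of 0.213, -0.205 and -0.138 for replicates 1 to 3 in fibroblast-like cells, 0.207, -0.340 and -0.347 in macrophage-like cells and 0.136, -0.477 and -0.277 in endothelial-like cells. LPT_MET 3 correlated best with LPT_WT 2, at 0.460, 0.684 and 0.726 in the same order of classes. Both libraries were made with Cell Ranger 3.1.0.

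With 1 library left out the counts ranged from 0 to 294 for fibroblast-like genes (294 without LPT_MET 3, 2 without LPT_WT 2, 1 without LPT_MET 1 or 2), from 0 to 315 for macrophage-like genes (315 without LPT_MET 3, 90 without LPT_MET 4, 2 without LPT_MET 1, 1 without LPT_MET 2) and from 0 to 22 for endothelial-like genes (22 without LPT_MET 4, 17 without LPT_MET 3, 2 without LPT_MET 1) of LPT_MET against LPT_WT. By burden they ranged from 0 to 69 for fibroblast-like genes (69 without LPT_MET 1, 15 without LPT_MET 3, 2 without LPT_MET 2) and from 4 to 56 for tumour-like genes (4, 56, 8 and 18 without LPT_MET 1 to 4). In tumour-like cells each of these fits by burden sets 1 library against 2, and the lone library is assumed to vary like the others, so they say little about stability. With 1 mouse left out they ranged from 0 to 5 for tumour-like genes (5, 1, 0 and 2 without mice 1 to 4) and from 10 to 2014 for macrophage-like genes (10, 147, 133 and 2014 without mice 1 to 4). The logit difference of the tumour-like share stayed between 7.60 and 9.40 against LPT_WT and between -2.69 and -1.28 against Primary, each at the smallest exact permutation p its splits allow. The logit difference of neuron-like cells ranged from -1.63 to 0.96 (without LPT_WT 3) and that of oligodendrocyte-like cells from -0.0861 (without LPT_WT 2) to 1.67.

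In the Pi16 cluster alone edgeR called 2 fibroblast-like genes and in the Tgfbi cluster 1, and in the Cxcl2 cluster 38 macrophage-like genes. In the Tgfbi cluster these turned: Aldh1a2 (-0.33), Col18a1 (-0.42), Col4a1 (-0.45), Col4a2 (-0.45), Nid2 (-0.15), Nrp1 (-0.71), Pdgfrb (-0.0143), Gli1 (0.10) and the basement membrane list (-0.22), and by burden Pdgfra (-0.33), Pdgfrb (-1.36), Ptch1 (0.40) and the camera direction of the growth factor list (-0.25). In the Pi16 cluster Bmp5 (0.45) and Pdgfa (-0.44) turned. Fibroblast-like Pdgfa turned to -0.0588 with doublets kept, Pdgfra and Pdgfrb by burden to -0.14 and -0.0648 with clusters of more called doublets named, and Mki67 of tumour-like cells in LPT_MET against Primary to -0.0332 with the stricter cell filter. As shares among all cells, T and NK-like (-0.21), dendritic-like (-0.0209), fibroblast-like (-0.0355), macrophage-like (-0.0223) and oligodendrocyte-like cells (-0.0193) turned.

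Some changes turned when 1 library was left out, most of them small. In tumour-like cells by burden Atoh1 ranged from -0.59 (without LPT_MET 4; -0.04 without LPT_MET 3) to 0.72, Gli1 from -0.43 (without LPT_MET 4; -0.37 without LPT_MET 1) to 1.38 and Mki67 from -0.10 (without LPT_MET 1) to 1.74. In fibroblast-like cells by burden Bmp4 ranged from -1.24 to 0.34 (without LPT_MET 1), Bmp7 from -0.90 to 0.30 (without LPT_MET 1), Pdgfra from -0.33 (without LPT_MET 4; -0.25 without LPT_MET 3) to 0.50, Pdgfrb from -0.48 (without LPT_MET 3; -0.43 without LPT_MET 4) to 1.13 and Ptch1 from -2.52 to 0.0605 (without LPT_MET 3). Tumour-cell transcripts in fibroblast-like cells ranged from -0.88 (without LPT_MET 4; -0.19 without LPT_MET 3) to 2.72. Blood transcripts in tumour-like cells ranged from 2.34 (without LPT_MET 3, where the camera direction turned) to 4.19. In tumour-like cells of LPT_MET against Primary Mki67 ranged from -0.10 (without mouse 3; -0.09 without mouse 2) to 0.13, Pdgfra from -0.57 (without mouse 2; -0.04 without mouse 1) to 0.58, and Pdgfa turned to 0.15 without mouse 3. Endothelial-like Pdgfd ranged from -0.25 (without LPT_MET 1) to 0.54. Medians of lists turned as well, to -0.0948 for matrix proteases in fibroblast-like cells without LPT_WT 2 and to 0.0449 for type I interferon genes in matched macrophage-like cells without mouse 4. Medians that turned for lists not called were those of leptomeningeal identity (-0.28 without LPT_MET 3) and of BMP ligands (-0.21 without LPT_WT 2) in fibroblast-like cells. In the matched comparisons they were those of hedgehog (-0.0878 without mouse 1) and proliferation genes (-0.0818 without mouse 4) in tumour-like cells and of hypoxia genes (-0.26 without mouse 3) in macrophage-like cells.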

Other observations

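The tests of the blocks along chromosome 8, of the other autosomes and of the match to the primary tumour below were chosen only after the result was seen, and the test of cells without Xist was written before its value.

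Levels of PDGF and BMP genes follow by cell class of the leptomeninges. Pdgfa was highest in mural-like cells (406 ± 76.1 CPM in LPT_MET, 388 ± 95.1 in LPT_WT) and Schwann-like cells (325 ± 42.1 and 277 ± 33.8), with 85.9 ± 26.1 in tumour-like cells of LPT_MET, all without TMM factors here. Pdgfb was at 151 ± 34.1 and 163 ± 25.3 in endothelial-like cells and at 29.9 ± 10.7 and 29.3 ± 7.06 in macrophage-like cells. In LPT_WT it was higher, at 217 CPM, in microglia-like cells. The receptor Pdgfra was in fibroblast-like cells (373 ± 112 and 289 ± 68.7), and Pdgfrb in mural-like cells (331 ± 142 and 267 ± 108) and fibroblast-like cells (239 ± 111 and 80.6 ± 24.3). Bmp4 (154 ± 54.1 and 61.7 ± 16.9) and Bmp7 (116 ± 26.1 and 61.7 ± 17.4) were highest in fibroblast-like cells of both tissues.

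Of 4 further classes compared between LPT_MET and LPT_WT, dendritic-like cells had the highest count, with 207 of 4764 genes past edgeR BH adjustment (81 higher and 126 lower). With 1 library left out this count was 122, 137, 136 and 389 without LPT_MET 1 to 4 and 116, 18 and 34 without LPT_WT 1 to 3. The higher genes included Il12b (log2 change 10.69 (1.05), 260.9 ± 109 against 0 CPM), Fscn1 (6.004 (0.92), 182 ± 107 against 1.47 ± 2.55), Ramp3 (4.28 (0.66)) and Itgae (3.66 (0.52), 136 ± 41.1 against 7.42 ± 10.3). The lower genes included Ms4a1 (-3.86 (0.49), 42.7 ± 29.2 against 566 ± 121 CPM), Pax5 (-4.27 (0.60), 13.1 ± 16.6 against 184 ± 41.7), Vpreb3 (-5.90 (0.78)) and Fcer2a (-6.76 (0.58), 1.97 ± 1.96 against 149 ± 29.8). Ms4a1 and Vpreb3 are in the set of B-cell markers fixed beforehand, so the class may hold B cells as well. In T and NK-like cells 10 of 5742 genes passed, 7 higher, of which 6 failed the background criterion, and 3 lower (2, 9, 1 and 17 without LPT_MET 1 to 4, and 4, 0 and 0 without LPT_WT 1 to 3). The lower ones were Lef1 (-2.22 (0.36), edgeR BH adjusted p = 0.0402), Dapl1 (-3.73 (0.51), edgeR BH adjusted p = 0.0238) and Rps21 (-1.54 (0.27), edgeR BH adjusted p = 0.0495). In mural-like cells 2 of 12045 genes passed, both failing the background criterion (0 to 7 with 1 library left out: 1 and 7 without LPT_MET 2 and 3, and 0 without LPT_WT 1, 2 or 3). In Schwann-like cells 0 of 11598 passed (486 at an unadjusted p under 0.05). With 1 library left out they were 3, 32, 14 and 7 without LPT_MET 1 to 4 and 0, 0 and 1 without LPT_WT 1 to 3. The 4 classes gave 219 genes in edgeR and 511 in DESeq2.

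In mouse 2 the tumour-like cells of the primary tumour had more transcripts of chromosome 8 (6.44% of UMIs) than those of the metastasis (4.63%) and of every other tumour (4.18% to 4.54%), and only the metastasis lacked Xist, so the primary tumour may hold an extra copy of chromosome 8 and the metastasis a clone that parted from it and lost its inactive X. A few neighbouring genes under shared regulation are argued against, because 10 of 10 blocks along the chromosome had medians below -0.3, and so is a difference in depth, because the largest other autosome was at 0.0580. A mislabelled library is argued against by a correlation of 0.55 with the own primary tumour outside chromosomes 8 and X, the highest with another being -0.06. Among Primary 2 cells with at least 3000 UMIs, the 273 of 6268 without Xist had a median of 6.29% of UMIs on chromosome 8, near that of the cells with Xist, which argues against those cells as the source of the metastasis. A rarer clone remains possible, because 56 of 6268 cells lay below the midpoint of 5.53% and 9 of these had no Xist, and DNA sequencing of both tissues would tell.

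In mouse 1 tumour-like cells without Xist had more transcripts of chromosome 6 than those with Xist, in the metastasis (5.97% in 474 cells against 4.30% in 1359 cells) and in the primary tumour (5.60% in 1125 cells against 4.00% in 5036 cells), so that 2 groups of tumour-like cells were present in both tissues. In Primary 3 the quartiles of chromosome 6 were 4.10% and 5.36% in cells with Xist, and in LPT_MET 3 3.67% and 4.13%.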
